A study of Gallus gallus with 7 samples.

How the data were processed

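Ovarian RNA of 7 hens, 3 persistent (PL) and 4 non-persistent (NPL), was measured by RNA sequencing, with one library per hen. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column with DNase treatment, and made into libraries with an NEBNext Ultra II kit whose name is given with "Directional" in brackets. The strand setting used in counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. Per the submitters' processing notes, Trim Galore and the genome build galGal6 were used; the aligner, the counting tool and the annotation release are not given in the sources used here. The authors deposited one table of raw read counts for 24356 Ensembl gene IDs and 7 libraries; the values are whole numbers with no normalization, the libraries were not pooled, and every row is a gene. Of these genes, 2410 had no count in any library.

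Each column was tied to its hen by the column name that the sample's own label states, and each hen to its group by the sample title. Sample numbers differ between the groups, so no pairing exists, and the labels give no batch. Libraries were checked for duplicates with a chi-square statistic over genes with at least 20 counts in a pair: over the 21 pairs it was between 17.0 and 163 per degree of freedom, where sampling noise gives a value near unity, so all 7 were kept as separate samples. Total counts were between 21535850 and 27803563, a ratio of 1.29.

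Gene names could not be attached. The reference table given for this work, of another assembly (GRCg7b), holds an Ensembl ID for 0 of its 25635 genes, so the 24356 IDs could not be compared with it. Before the data were examined, 37 gene lists (1100 symbols) and a rule for the genes to be named were fixed. Both need symbols, so the lists were not tested, and the shares of mitochondrial, ribosomal protein and haemoglobin transcripts planned as quality measures were not computed. In place of the rule, the 2 IDs with the smallest p-value in each direction are printed. No coordinates, gene lengths or GC contents were used.

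The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, with genes kept by filterByExpr (17051 kept, 7305 left out), TMM factors (0.956 to 1.04), robust dispersion shrinkage and the model of group alone. Fold changes are PL relative to NPL, standard errors were taken as the log2 fold change over the square root of the F statistic, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was an adjusted p of 0.05. CPM values are scaled by TMM factors, and principal components were taken from log2 CPM with a prior count of 2. Single measures per hen were compared by exact permutation over the 35 splits of the 7 hens into 3 and 4, with the absolute difference of group means as the statistic. The hens are separate animals, so p-values measure the spread between birds. Each hen gave a single library, so this spread includes differences in tissue sampling, RNA extraction and library preparation. The common biological coefficient of variation was 0.255.

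The tests were tried on simulated data. Counts were drawn for the 17051 genes of the PL against NPL comparison from their real means, dispersions and library sizes, with 200 genes of at least 5 CPM changed by 2-, 4- or 8-fold, in 5 draws. edgeR recovered 65.4%, 95.5% and 99.4% of these changes and called a median of 12 unchanged genes, and DESeq2 recovered 84.2%, 97.9% and 100% and called a median of 58 unchanged genes. With no gene changed, edgeR called 0 genes in each of 5 draws and DESeq2 called between 7 and 22. The same changes were also imposed on the real counts by binomial thinning, which keeps the real differences between hens.

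Alternatives fixed beforehand were DESeq2 size factors, library size alone, no low-count filter, a filter of 1 CPM in 3 libraries, the DESeq2 Wald test (DESeq2 1.42.0), limma voom with sample quality weights (limma 3.58.1), no robust shrinkage, an adjusted p of 0.10, and leaving out each hen in turn, for the counts of genes past the threshold, the named genes and (top 10 and 200 genes, and each hen left out) the composition. For the number of genes with an unadjusted p under 0.05, the share of intervals within 2-fold and the first component, these same settings were applied only after seeing the data, and not all of them. The adjusted p of 0.10 was applied to none of these results. The share of intervals was not taken from DESeq2 or limma voom. The first component was not taken from DESeq2, limma voom or the fit without robust shrinkage. Also added after seeing the data were the first component or 1 surrogate variable (sva 3.50.0) as a covariate, DESeq2 with each hen left out, DESeq2 without independent filtering, and DESeq2 on only the genes kept for edgeR. Leaving out genes that take over 1% of a library was planned but removes nothing, since the most abundant gene took at most 0.956% of any library.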

Results

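RNA from the ovary of 7 laying hens was sequenced to ask which genes are expressed differently in hens that keep laying late in life. The birds were Single-comb White Leghorns, an egg-laying breed, drawn from a flock of 40 whose eggs were recorded daily from week 16 to week 76. Hens of the upper quartile of laying were called persistent (PL, n = 3, laying rate 100%). Hens of the lower quartile were called non-persistent (NPL, n = 4, laying rate at most 82%). The tissue was about 10 mg of the ovarian body, stripped of follicles larger than 1 mm, so that the larger, yolk-filled follicles were not included. Each library came from a separate hen, named here by the sample number in its label: hens 8, 9 and 20 were PL, and hens 10, 12, 13 and 42 were NPL.

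The libraries held between 21535850 (hen 42) and 27803563 (hen 10) counts over 24356 Ensembl genes. One count corresponded to between 0.0360 and 0.0464 CPM (the count scaled to the library total), and a gene with no count in a library could still lie at up to 0.139 CPM in the shallowest one (3 counts, counting error only). Total counts did not differ detectably between PL (24002906 ± 1903997, SD, n = 3) and NPL (24904803 ± 2928744, SD, n = 4; exact permutation test, two-sided, p = 0.686). The number of genes with at least 1 count was 20048 ± 105 (SD, n = 3) in PL and 20073 ± 182 (SD, n = 4) in NPL (exact permutation p = 0.857). The 50 most abundant genes took 10.1% ± 1.91 (SD, n = 3) of the counts in PL and 10.8% ± 1.37 (SD, n = 4) in NPL (exact permutation p = 0.543). All 3 measures had a Benjamini-Hochberg adjusted p of 0.857 over this family of 3, and 35 splits of the 7 hens allow an exact p no smaller than 0.0286.

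Expression in the ovary did not differ detectably between persistent and non-persistent hens for any gene by the main test. Of 17051 genes tested, 0 were higher and 0 were lower in PL at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment; the smallest adjusted p was 0.886). This distance from the threshold depends on the hens and the model: the smallest adjusted p was 0.081 without hen 8, 0.428 without hen 9 and 0.999 without hen 20, and 0.140 with the first component of expression as a covariate. Fold differences between the group means were small: the median absolute log2 fold change was 0.17, 95% of the genes lay under 0.71, and 98.1% of the genes differed by less than 2-fold. The 332 genes that differed by 2-fold or more did not pass the test either. At an unadjusted p under 0.05 there were 600 genes, 270 higher and 330 lower in PL, which is 3.52% of the genes tested. Unchanged genes with well-calibrated p-values would give 5% on average, but the count varies widely with the hens compared: the other splits of the same hens gave a median of 417.5 such genes, and the count was 3346 without hen 8 and 329 without hen 20. DESeq2, a second count test, called 11 genes at an adjusted p under 0.05, 7 higher and 4 lower in PL, and limma voom with sample quality weights called 0, with a smallest adjusted p of 0.0593, while giving 4854 genes an unadjusted p under 0.05. The limma voom test was run neither on simulated counts nor over the splits of the hens, so how many genes it gives without a group difference is not known here.

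The intervals of the fold changes show how large a difference these hens leave room for. The median standard error of a log2 fold change was 0.22. For 12116 genes (71.1%) the 95% confidence interval lay wholly within 2-fold in either direction, and for 95.8% it lay within 4-fold. Among the 12617 genes with a mean of at least 5 CPM, 87.7% had an interval within 2-fold and 99.3% within 4-fold. When known changes were imposed on these same 7 libraries by thinning the counts of 200 genes at a time, edgeR recovered 56.4% of the 2-fold changes, 91.0% of the 4-fold changes and 97.9% of the 8-fold changes. A single changed gene among 17051 unchanged ones is harder to call: 0.896% of the 2-fold, 48.7% of the 4-fold and 72.4% of the 8-fold changes had a p-value small enough to pass alone.

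The genes with the smallest p-values separated the groups without overlap, which their selection by p-value favours, but did not pass the edgeR adjustment. ENSGALG00000049250 had the smallest p of all genes, with 7.44 ± 2.13 CPM (SD, n = 3) in PL and 1.64 ± 0.529 CPM (SD, n = 4) in NPL, a log2 difference of 2.17 (SE 0.33) or 4.50-fold. ENSGALG00000048197 lay at 9.59 ± 1.53 CPM in PL and 2.58 ± 1.22 CPM in NPL, a log2 difference of 1.89 (SE 0.38). In the other direction, ENSGALG00000030151 lay at 2.09 ± 0.698 CPM in PL and 9.57 ± 3.24 CPM in NPL, a log2 difference of -2.19 (SE 0.37). ENSGALG00000053144 lay at 0.390 ± 0.0839 CPM in PL and 1.92 ± 0.703 CPM in NPL, a log2 difference of -2.28 (SE 0.42), with between 8 and 64 counts per library. The edgeR adjusted p of each was 0.886 and the limma voom adjusted p of each was 0.0593. DESeq2 gave these genes adjusted p-values of 3.99e-06, 0.00196, 2.27e-05 and 0.00725 in the order named, so their calls depend on the test. The count table identifies genes by Ensembl ID and no pairing of these IDs with symbols or positions was used here, so the functions and locations of these genes are not given.

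**Figure D1:**
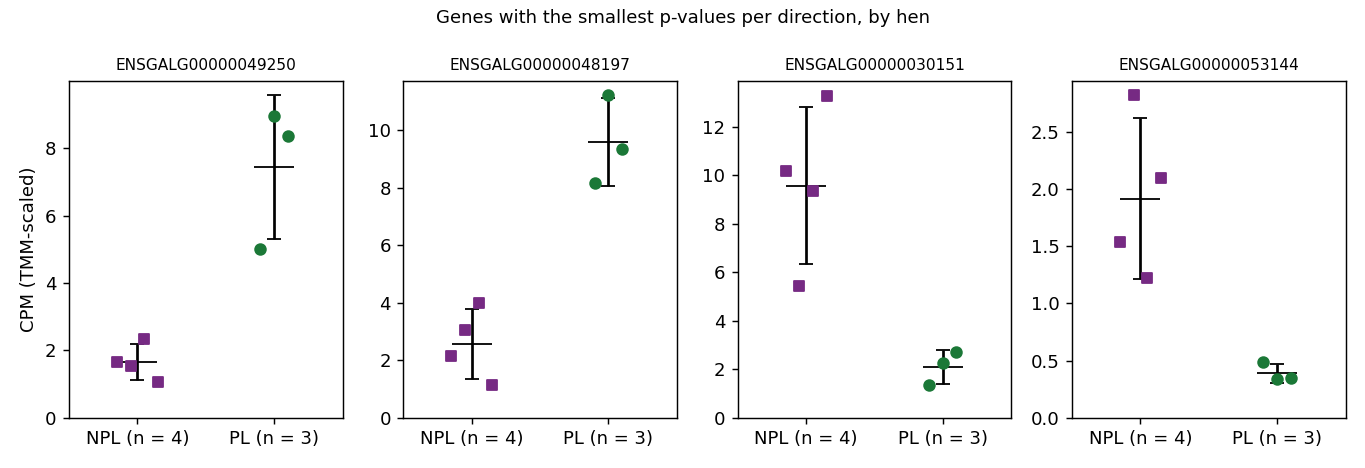
TMM-scaled CPM (vertical axes, linear, from 0) of the genes with the smallest edgeR p-values in each direction, by group (horizontal axes). Each point is one hen, the horizontal bar is the group mean and the whisker is 1 SD. The PL and NPL hens do not overlap in any panel, which the selection of genes by p-value favours, and each gene has an edgeR adjusted p of 0.886.

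Among all genes tested, 703 had CPM ranges that did not overlap between the groups, 346 with every PL hen above every NPL hen and 357 with every PL hen below. These were 4.12% of the genes, where 5.71% is the share that chance gives for 3 hens against 4. Of the 11 genes that DESeq2 called, 10 were free of overlap on a plain CPM scale, which selection by a small p-value favours. In 3 of the 11, all of them higher in PL, hen 20 alone held more than 80% of the summed PL value. Of the 11, 3 were below the expression filter of the edgeR fit. The other 8 were tested by edgeR and had an unadjusted p under 0.05 there. Without hen 20, DESeq2 called 2 genes; without hen 8 it called 909 genes, 276 higher and 633 lower in PL, whereas edgeR called 0 in either case.

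The largest axis of variation among the hens did not separate the labelled groups. The first principal component of log2 CPM carried 40.1% of the variance. Hens 9, 20 and 13 had scores of 55.3, 27.5 and 27.6 on it, and hens 10, 12, 42 and 8 had scores of -10.4, -31.9, -33.3 and -34.8. PL hen 8 therefore lay among the NPL hens and NPL hen 13 among the PL hens, and the group means of 16.0 ± 46.2 (SD, n = 3) for PL and -12.0 ± 28.4 (SD, n = 4) for NPL did not differ detectably (exact permutation test, two-sided, p = 0.371). Components 2 and 3 carried 16.1% and 15.1% of the variance, and the groups did not differ detectably on these either (exact permutation p = 0.971 and p = 0.143; adjusted over the 3 components, 0.557, 0.971 and 0.429 in order). The mean Pearson correlation of log2 CPM across genes was 0.972 over the 9 pairs of hens within a group and 0.971 over the 12 pairs from different groups. Splits of the hens gave a gap at least that large in 11 of 35 cases (exact one-sided p = 0.314). The scores of the first component moved with the share of counts in the 50 most abundant genes: this share was 8.52%, 9.55% and 8.84% in hens 9, 20 and 13, and between 11.0% and 12.2% in the other 4 hens.

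**Figure D2:**
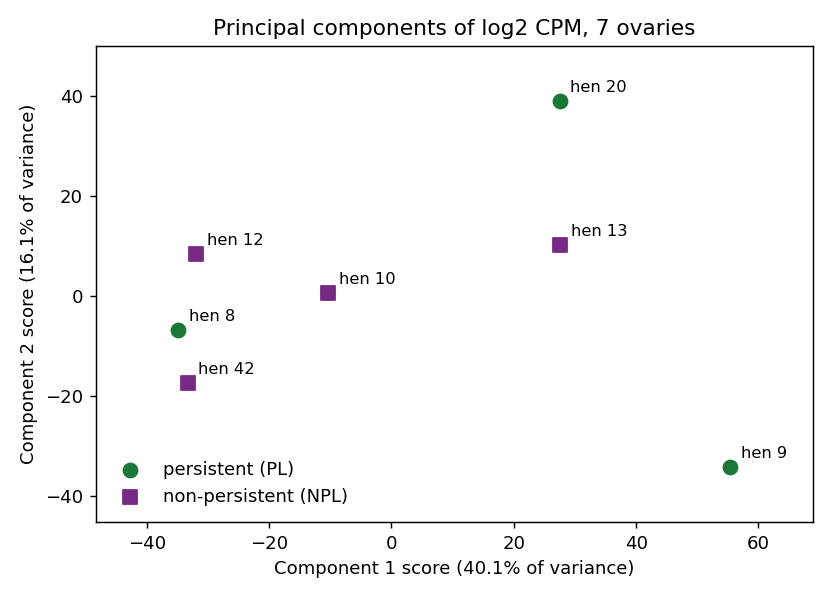
Scores of the 7 ovaries on the first (horizontal, 40.1% of the variance) and second (vertical, 16.1%) principal components of log2 CPM over 17051 genes; each point is one hen, circles are PL and squares NPL. Hen 8 (PL) lies beside NPL hens 12 and 42, and hen 13 (NPL) lies at the same position on the first component as PL hen 20.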

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

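The count of 0 genes in each direction by edgeR held under each alternative scaling, filter, shrinkage, covariate and threshold run with edgeR, with each hen left out, and by limma voom; the DESeq2 Wald test was the exception, with 7 higher and 4 lower, without its independent filtering 4 higher and 4 lower, and on the 17051 genes kept for edgeR 4 higher and 5 lower. The smallest adjusted p by edgeR (0.886) moved more than the count did: it was 0.081 without hen 8, 0.428 without hen 9, 0.632 without hen 13, 0.140 with the first component as a covariate and 0.227 with a surrogate variable; it was 0.0593 by limma voom. Leaving out 1 hen moved the DESeq2 counts to between 1 and 276 higher and between 1 and 633 lower. Its total was 909 without hen 8, 41 without hen 9, 14 without hen 13, 8 without hen 10, 7 without hen 12, 6 without hen 42 and 2 without hen 20. Without hens 8, 9 or 20, respectively 11, 8 and 2 of the original 11 calls were kept. Without hens 10, 12, 13 or 42, respectively 6, 6, 6 and 5 of them were kept. The next results were put through the alternatives that yield them only after seeing the data: the number of genes with an unadjusted p under 0.05, the share of intervals within 2-fold and the group difference on the first component. The number of genes with an unadjusted p under 0.05 by edgeR (600) was between 329 and 3346 with 1 hen left out: 3346 without hen 8, 1107 without hen 13, 349 without hen 10, 359 without hen 12 and 329 without hen 20. It was 988 with the first component as a covariate, 966 with a surrogate variable and 4854 by limma voom. The cause of these shifts was not tested. The share of genes whose interval lay within 2-fold ranged from 55.8% without a low-count filter to 77.2% with the filter of 1 CPM. The PL minus NPL difference in the share of counts in the 50 most abundant genes changed sign only without hen 9. It ranged from -1.78 to 0.064 percentage points with 1 hen left out. Its exact permutation p was 0.267 to 1 over the alternatives, against 0.133 to 0.8 for the first component. With 1 hen left out neither p can fall under 0.05. The fold changes of the named IDs kept their direction under all 16 alternatives and passed the threshold only by DESeq2. Leaving out a hen could hardly reverse them, since the IDs were picked by p-value and their groups do not overlap. The planned list tests were not run because the IDs could not be paired with symbols. The alternative without genes above 1% of a library changes nothing by construction.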

Other observations

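In this part, the tests of the hens' positions after thinning, of leaving out the abundant genes and of DESeq2 over the splits of the hens were specified before their results were seen; the others were chosen afterwards, as were the range with each hen left out and the shuffled reference for the abundant genes. Outlier checks (Dixon's ratio, 12 values in the 4 NPL hens) marked 0 values, and groups of 3 such as PL were not checked.

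Hens 20 and 9 had genes far above every other library. In hen 20, 14 genes lay at least 8-fold above every other library, with at least 1 CPM and the other libraries set to no less than 3 counts. Hen 9 had 2 such genes and the other 5 hens had 0. At 4-fold the numbers were 31 in hen 20, 14 in hen 9, 3 in hen 12, 2 each in hens 10 and 42, 1 in hen 8 and 0 in hen 13. The biological coefficient of variation was 0.300 among the 3 PL hens and 0.219 among the 4 NPL hens, a ratio of 1.37, but 6 of the 35 splits of the hens gave a ratio at least as far from equality (p = 0.171, exact, two-sided), so chance is not excluded.

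The largest pattern in these data runs across the labelled groups: hens 9, 20 and 13 stood apart from hens 8, 10, 12 and 42. Of the 35 splits of the hens, the one along this line gave 4436 genes past the edgeR threshold, 2194 higher and 2242 lower in hens 9, 20 and 13, with a median absolute log2 difference of 0.55; the labelled split gave 0, and the other splits gave at most 3. This count comes from a split picked for its size, so it describes a structure of the samples and tests no hypothesis. Sequencing depth is argued against by the order of the totals: the deepest (hen 10) and the shallowest library (hen 42) lie on the same side. Hens 20 (22312114 counts) and 13 (26853001 counts) lie together on the other side. After every library was thinned to 21535850 counts, the split along this line still gave 4369 to 4440 genes past the edgeR threshold over 5 draws. In a draw, 142 to 184 of the 4436 calls were lost and 117 to 146 gained. This count decides little, since edgeR already scales by library totals. The correlation of the hens' positions before and after thinning (r = 0.9998 or more) decides nothing, since totals that differ by a ratio of 1.29 leave it near unity. A pattern carried by only a few abundant genes is argued against as well. Of all 17051 genes, 3250 (19.1%) followed the component with an absolute r over 0.9. Leaving out 200 genes cannot remove that many, so the share after leaving them out decides nothing further. Without the 200 most abundant, which held 20.0% of the counts, 18.7% of the genes left (3151) followed the component. This share was between 15.4% and 23.0% with each hen left out and at most 0.720% with the hens shuffled within each gene. Shuffling removes any shared pattern, so that reference gives only the share that chance reaches. A high r is easier to reach with fewer hens, so chance gives a larger share with a hen left out. The positions themselves (r = 0.99999) decide nothing here, since so few of 17051 genes can hardly move them. Counts that abundant genes take up leave room for a small shift: over the range of the component the other 16851 genes rose by a median of 0.121 log2 on plain CPM (quartiles, -0.360 and 0.535), near the 0.117 log2 that the share left to them allows between hens. As the whole of the pattern this shift is argued against, since scaling by the totals left without those 200 genes moved the log2 differences along the line by a median of -0.082 and still left 4227 calls, 2120 higher and 2107 lower, against 4527 with full totals. Laying persistency as labelled cannot be the whole of it, since hen 8 and hen 13 each lay on the other group's side (exact permutation p = 0.371 for the group difference). Leaving out hen 8 or 13 brought the labels closer to this line. The PL minus NPL difference on the first component (28.0) was 57.1 without hen 8 and 42.0 without hen 13. With another hen left out the difference was 13.9 to 27.7, and 329 to 424 genes had an unadjusted p under 0.05. The component was refitted on the hens left each time, so its scale can differ and these differences compare only roughly. The 3346 such genes and 909 DESeq2 calls without hen 8 therefore cannot be separated from this line. Whether this line accounts for the 988 genes with the component as a covariate was not tested. An exchange of labels between hens 8 and 13 would make the line match the groups, but 13 of the 35 splits lie within 1 exchange of the labels, so a line this close to them is common by chance and the exchange cannot be told apart from a real difference between hens; region sampled, stage of the laying cycle, RNA quality, GC content and gene length were not tested.

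The labelled comparison was set against the other splits of the same hens. For the 0 genes that edgeR called, 35 of 35 splits reach that count whatever the data (highest other, 4436), so it says nothing about chance. Of the other counts, 12 of 35 splits gave at least the 600 genes with an unadjusted p under 0.05 (highest other, 6888), and 14 of 35 gave at least the 11 genes that DESeq2 called (highest other, 5631; median of the others, 5). Chance is therefore not excluded for the 600 and the 11. A candidate explanation for the DESeq2 calls is that this test calls unchanged genes with so few hens: in simulated counts of the 17051 genes kept for edgeR, with no gene changed, it called a median of 18 genes (7 to 22 over 5 draws), while edgeR called 0. On these same genes the real comparison gave 9 DESeq2 calls, 8 of them among the 11, and the other 3 of the 11 were not in the simulated set. The simulated genes varied independently of one another, whereas many real genes share the first component. Only numbers of calls were compared, so the simulation does not address how small a single DESeq2 adjusted p was, such as 3.99e-06 for ENSGALG00000049250. This leaves open whether single genes among the 11, such as ENSGALG00000049250, differ between laying groups, which needs more hens to decide.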
